A study of Rattus norvegicus with 24 samples.

How the data were processed

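Gene expression was measured by RNA sequencing in 24 libraries from rats, 4 rats in each of 6 groups. The labels do not say whether the same rats gave kidney and heart. Per the labels, the tissues were the papilla (inner medulla) of the kidney and a piece of the heart ventricle, and the Sprague-Dawley rats weighed 120 to 200 g. Rats ate a synthetic diet for 7 days with a Na content of 0.4% or of 0.01 to 0.02%. In a separate kidney experiment, rats on 0.4% Na carried an osmotic minipump that released aldosterone at 12 µg per day, or served as controls. The 0.4% diet is named a control diet in the protocol and high salt in the sample titles, and the latter name is used here for the low-salt experiment. Groups, replicate numbers and batches were taken from the titles and characteristics: replicates 1 and 2 of every group belong to batch 1, and replicates 3 and 4 to batch 2.

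Per the labels' protocols, the libraries were made with a stranded mRNA kit (TruSeq) and sequenced with 50 cycles from 1 end on a NovaSeq X Plus. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic, Salmon and MultiQC, and their settings, the genome build, the annotation and the strand setting are not given in the sources used here. The authors deposited expected counts (estimated read counts that need not be whole) for 36856 genes in 3 tables, 1 per experiment and tissue, not scaled to a common total. All 24 columns were matched to samples by name. All 36856 gene symbols occur in a RefSeq gene table of the GRCr8 assembly, which was used for names only, and no coordinates are given. Short reads that fit several near-identical genes, such as the globin genes or the aldose reductase family with Akr1b1 and Akr1b8, are shared out by estimation, so the values of single members of such families are uncertain.

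The expected counts were rounded to whole numbers. Each table was fitted on its own with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood F test (glmQLFit, glmQLFTest) compared the groups with batch as a term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05 and no fold minimum. Levels are normalised CPM (counts scaled to the effective library size) with the SD over 4 rats, and log2 fold changes carry the standard error of the fit. Differences between responses were tested as an interaction over 16 libraries, with an intercept for each table and batch. Gene lists with at least 3 measured members were tested on log2 CPM with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. List p-values were adjusted over the lists of a comparison. The design, the 40 gene lists, the rule for named genes and the list of alternatives were fixed before the data were examined. The rule names up to 6 genes per direction with the largest fold among genes past the threshold, at 1 CPM or more and with the same direction in both batches, up to 3 members per list that passed, a fixed set of corticosteroid, Na transport and cardiac genes whatever their p, and the 4 genes with the smallest p in each interaction. Where fewer than 5 genes passed, the 5 smallest p-values of each direction are named. Further list members given below, such as Mki67, Ccnb2, Col1a1, Thbs1, Ankrd1 and Acadm, lie outside this rule. Their choice was not fixed beforehand, some are the extremes of their lists, and they are not among the named genes counted in the alternative fits. A gene of the fixed set is not reported here.

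Library totals ran from 24299000 to 38319000 counts, so a gene at 1 CPM has at least 24 counts in a library. Some named genes lie below that level in a group, such as Ces2e and Shisa2 in kidney on low salt, and counting error adds to their spread. Recovery by the tests was checked on simulated counts with 200 changed genes, drawn independently for each gene and library. Shifts shared by many genes or by a library are not in the simulation. The shares below hold for that setting and do not give the power in these data. In the aldosterone comparison 29.9%, 55.2% and 90.9% of genes changed 1.5, 2 and 4-fold were recovered, with 16 false calls among 133. In the kidney low-salt comparison the shares were 38.8%, 73.1% and 87.9%, with 7 false calls among 140, and in heart 40.3%, 59.7% and 87.9%, with 4 among 129. For the interaction of aldosterone and low salt they were 8.96%, 43.3% and 72.7%, with 3 false calls among 86, and for that of kidney and heart 13.4%, 37.3% and 66.7%, with 1 among 79. No pair of libraries of 1 group agreed within sampling noise, with chi-square values per gene of 22.3 to 116 over 36 pairs.

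Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors and upper quartile scaling in edgeR, no filter and a filter of 1 CPM in 4 libraries, no batch term, the replicate number as a block, each library left out in turn, glmTreat against a fold of 1.2, an adjusted p under 0.10, and limma-voom with sample weights. Fits of each batch alone, a fit with the rat as a block across tissues, DESeq2 calls in the overlaps and 4 further gene lists were added after the data had been seen. In heart, the deviations of same-numbered libraries from their group means correlated across genes at 0.223 to 0.296 in the 4 pairs, all above the minimum of 0.1 set for treating numbers as pairs. Heart libraries with other numbers of the same batch correlated at 0.258 to 0.325, and those of different batches at -0.342 to -0.156, so the shared batch gives such values without any pairing. The blocked values stand beside the heart results. In the kidney experiments at least 1 pair lay below 0.1, and the numbers were not treated as pairs.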

Results

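Dietary Na restriction raises the plasma level of the adrenal steroid aldosterone, which acts on the distal parts of the nephron to retain Na. The data set measured how gene expression in the kidney inner medulla and the heart ventricle depends on Na intake, and how the inner medulla responds to aldosterone given without a change of diet. Aldosterone-infused rats were compared with controls on the same 0.4% Na diet, and rats on low salt (0.01 to 0.02% Na) with rats on high salt (0.4% Na), each after 7 days and with 4 rats per group. The libraries held 24299000 to 30615000 counts in the aldosterone group and 26020000 to 30085000 in its controls. In kidney they held 30830000 to 32755000 counts on low and 34013000 to 38319000 on high salt, and in heart 26300000 to 32567000 and 27163000 to 30421000. Ribosomal RNA took 0.516% to 3.15% of the counts.

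The labels describe all rats as female. Xist, the RNA that coats the inactive X chromosome of females, stood at 239 to 454 CPM in the 8 libraries of the aldosterone experiment and at no more than 0.0912 CPM in the 16 kidney and heart libraries of the low-salt experiment. The summed level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 144 to 275 CPM in those 16 libraries and at most 0.319 CPM in the 8 others. The comparisons within an experiment hold libraries of 1 pattern only, and the comparison of aldosterone with low salt sets libraries of both patterns against each other.

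Low salt changed the kidney inner medulla widely: 201 genes were higher and 253 lower than on high salt among 18449 tested (edgeR, Benjamini-Hochberg adjusted p under 0.05). Scnn1a, which encodes the alpha subunit of the epithelial Na channel ENaC, rose from 25.4 ± 6.24 to 164 ± 59.5 CPM (SD, n = 4 rats), 6.34-fold, with an adjusted p of 0.0103. Zbtb16, a transcriptional repressor induced by corticosteroids, rose from 9.83 ± 2.01 to 50.1 ± 7.47 CPM, 5.06-fold, with the smallest adjusted p of 0.00539. Akr1b1, the aldose reductase that makes the osmolyte sorbitol and one of the more abundant transcripts of this tissue, fell from 9012 ± 1377 to 2692 ± 714 CPM, with a log2 fold change of -1.74 ± 0.19 (SE). Slc14a2, the urea transporter of the inner medullary collecting duct, fell from 1891 ± 387 to 1074 ± 153 CPM (log2 -0.81 ± 0.12). Of the genes called, 40 rose and 44 fell at least 2-fold. A provisional name alone (such as a LOC name) was given for 15 of those higher and 9 of those lower. Among the called genes, which were selected for a difference, 423 had no overlap between the 4 values of either diet. Over all genes tested the share was 11.4%, where chance gives 2.86%.

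Of the 20 measured corticosteroid-induced genes, 5 rose and none fell, and 18 had positive log2 fold changes, with a median of 0.48. Besides Zbtb16 these were Fkbp5, a co-chaperone of steroid receptors (log2 0.69 ± 0.12 SE), Errfi1, an inhibitor of the EGF receptor (0.52 ± 0.10), and the metallothioneins Mt1 (0.61 ± 0.13) and Mt2A (0.57 ± 0.12). Adjusted over the list alone, 9 members passed, among them the clock gene Per1 (log2 1.14 ± 0.24, adjusted p over all genes 0.0524). Sgk1, the kinase that mediates part of the response to aldosterone, stood at 1041 ± 76.7 CPM on low salt and 723 ± 248 CPM on high salt (adjusted p 0.237), and Tsc22d3, known as GILZ, at 0.12 ± 0.19 (adjusted p 0.762), so neither passed. The list test with the preset correlation gave an adjusted p of 1.84e-06 for the corticosteroid list, and the adjusted p was 0.866 with an estimated correlation. Fry's directional test gave an adjusted p of 0.07, and its test in either direction 0.000315. Per1 lay higher on low salt in both batches (log2 differences of 1.23 and 1.08), as did Zbtb16 (2.43 and 2.18).

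Among 28 genes of distal nephron Na, K and Cl transport, 2 rose and none fell over all genes tested, and 7 were higher and 2 lower when adjusted over the list alone. The second gene past the threshold was Klhl3, a substrate adaptor that controls the WNK kinases (log2 0.82 ± 0.15). The beta and gamma subunits of ENaC had log2 fold changes of 0.89 ± 0.20 for Scnn1b (adjusted p 0.0561) and 0.54 ± 0.13 for Scnn1g (0.0662), with all 4 values on low salt above all 4 on high salt. Hsd11b2, the enzyme that shields the mineralocorticoid receptor from glucocorticoids, stood at 0.63 ± 0.23 (0.176), and the receptor gene Nr3c2 at 0.10 ± 0.11 (0.688). The list passed with the preset correlation (adjusted p 0.0384) and had an adjusted p of 0.866 with an estimated correlation.

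**Figure D1:**
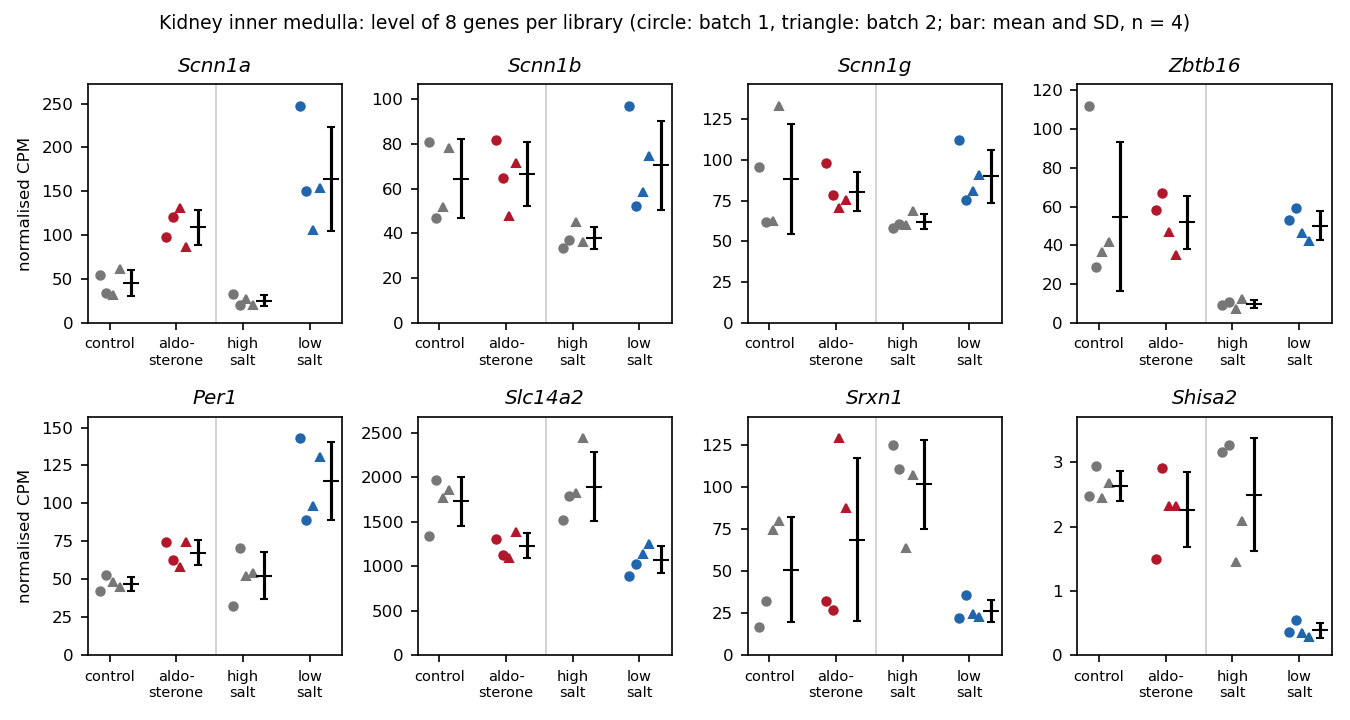
Normalised CPM of 8 genes in each kidney library, by group, for the aldosterone experiment (control, aldosterone) and the low-salt experiment (high salt, low salt). Circles are libraries of batch 1, triangles those of batch 2, and the black bars give mean and SD of 4 rats. The means of Scnn1a are 45.3 and 109 CPM in the aldosterone experiment and 25.4 and 164 CPM in the low-salt experiment.

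Genes that protect medullary cells from high osmolality moved in both directions. Of the 13 measured members, Nfat5, the transcription factor of the tonicity response, rose (log2 0.61 ± 0.08 SE), while Akr1b1 and the heat shock protein gene Hspa4l (-1.37 ± 0.24) fell, and 3 were higher and 3 lower when adjusted over the list alone. Slc6a12, the betaine transporter, had a log2 fold change of -1.55 ± 0.37 (adjusted p 0.0697) and Slc6a6, the taurine transporter, of 0.77 ± 0.18 (0.0662). The list as a whole had no direction (adjusted p 0.818), and fry's test for changes in either direction gave an adjusted p of 8.65e-05. Of the 12 water and urea transport genes Slc14a2 alone fell, and Aqp2, the vasopressin-regulated water channel, stood at 5412 ± 835 CPM on low and 6642 ± 621 CPM on high salt (adjusted p 0.276). That list had a median of -0.00 and an adjusted p of 0.663.

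The glycolysis and hypoxia list was lower on low salt, with 19 of 21 members negative and a median log2 of -0.20. The enolase gene Eno1 fell (-0.50 ± 0.10 SE), 4 members passed when adjusted over the list alone, and the adjusted p was 0.00266 with the preset and 0.866 with an estimated correlation. In the heat shock list 1 of 13 members fell, the small chaperone Cryab (-0.62 ± 0.09), and 4 were lower when adjusted over the list alone (adjusted p 0.0432 preset, and an adjusted p of 0.866 with an estimated correlation). Vcam1, an adhesion molecule for leukocytes, rose from 37.1 ± 10.2 to 95.7 ± 27.7 CPM as the only called member of the inflammatory list, and Ptgds, a prostaglandin D synthase, rose in the prostaglandin list (0.47 ± 0.10). Emcn, an endothelial sialomucin, fell (-0.75 ± 0.12), as did the interferon-induced gene Ifi44 (-0.47 ± 0.07), and Tyms, which makes thymidylate, rose (0.49 ± 0.09). The endothelial, interferon, inflammatory, prostaglandin and cell cycle lists that hold these genes did not pass (adjusted p 0.212, 0.561, 0.557, 0.623 and 0.177, with medians of -0.10, -0.06, 0.14, -0.03 and -0.21).

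The genes with the largest folds included Lrrn2 (log2 2.01 ± 0.29), Opcml (2.03 ± 0.41) and Gdpd2 (1.97 ± 0.40), and Ltb, which encodes lymphotoxin beta, a member of the TNF family (2.01 ± 0.30). The largest decreases were of the carboxylesterase Ces2e (-3.87 ± 0.60, from 2.91 ± 1.55 to 0.201 ± 0.126 CPM) and Shisa2 (-2.67 ± 0.24). Others were Pla2g7, a phospholipase that breaks down platelet-activating factor (-2.50 ± 0.39), Sphkap (-2.39 ± 0.29), Prss35 (-2.39 ± 0.43) and Akr1b8 (-2.20 ± 0.30), an aldo-keto reductase related to Akr1b1.

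Lists of other cell types and pathways are given as measured. The erythroid list was positive in 9 of 9 members with a median of 1.15 (adjusted p 0.0375, and an adjusted p of 0.866 with an estimated correlation), no member passing, and its median was -0.13 in batch 1 alone. Globin genes took 0.249 ± 0.0988% of the counts on low salt and 0.168 ± 0.153% on high salt. Proximal tubule markers had 10 of 10 positive values (median 0.78, adjusted p 0.163). Oxidative phosphorylation (median 0.07, adjusted p 0.0384), cholesterol synthesis (0.21, 0.0450) and ribosomal protein genes (0.14, 0.0432) passed with the preset correlation, each with an adjusted p of 0.866 with an estimated correlation and with no member called. The remaining lists did not pass, at medians of 0.49 for renin-angiotensin and corticosteroid receptors and enzymes, -0.03 for the circadian clock, 0.02 for immediate early genes, -0.19 for natriuretic peptide signalling, -0.03 for extracellular matrix, 0.03 for fatty acid oxidation and -0.07 for endoplasmic reticulum stress. Among cell type markers, the medians were 0.14 for principal cells, 0.38 for intercalated cells, 0.20 for the thick ascending limb, and 0.08 for the distal convoluted tubule. They were -0.37 for urothelium, -0.02 for smooth muscle, 0.02 for fibroblasts, 0.11 for adipocytes, -0.04 for macrophages and other leukocytes, 0.57 for neutrophils and 0.19 for nerve and Schwann cells. The median and the mean differed in sign for immediate early, prostaglandin, matrix, distal convoluted tubule, fibroblast, leukocyte and nerve genes, and the median and the test for immediate early and distal convoluted tubule genes. In all, 8 of 34 lists passed with the preset correlation, none with an estimated correlation, none by fry's directional test, and 15 by its test in either direction.

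The count of kidney genes rested on single libraries. It was 2 higher and none lower without low-salt replicate 3, 15 and 9 without high-salt replicate 2, 22 and 16 without high-salt replicate 3, and 36 and 34 without high-salt replicate 1. It was 45 and 39 without low-salt replicate 4, 100 and 63 without low-salt replicate 2, and 295 and 128 without low-salt replicate 1. Of the 29 named genes called, all kept their direction in these 8 fits, but only 2, Scnn1a and Zbtb16, passed in all 8. Eno1, Tyms, Gdpd2 and Ptgds passed in 0 of the 8. With the block 9 of the 29 passed, and without a batch term 18. DESeq2 called 777 higher and 829 lower genes, which included all 454, and the fit without a batch term gave 80 and 85. The batches alone gave none in batch 1 and 204 higher and 36 lower in batch 2.

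Infusion of aldosterone was compared with control rats on the same diet to show the response to aldosterone on its own. Among 17671 genes tested in edgeR, none passed the adjusted threshold, while 1096 were higher and 654 lower at an unadjusted p under 0.05, where chance alone gives 884 in all. Other splits of the same libraries gave up to 1586 such genes with each batch spread evenly and up to 2670 otherwise, against 1750 in the real split. That count therefore does not set aldosterone apart from such splits. DESeq2 called 297 genes higher and 62 lower. The smallest adjusted p, 0.0634, belonged to Prkcd, protein kinase C delta, at 101 ± 8.91 CPM with aldosterone and 57.0 ± 5.26 CPM in controls (SD, n = 4 rats). Scnn1a stood at 109 ± 20.1 CPM against 45.3 ± 15.2 CPM, a log2 fold change of 1.26 ± 0.25 (SE), with no overlap between the groups and an adjusted p of 0.182 in edgeR, and of 0.000104 in DESeq2.

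The cell cycle list stood furthest from 0: all 26 measured members had positive log2 fold changes with a median of 1.37, and all 26 passed when adjusted over the list alone, although none passed over all genes tested. Examples are the proliferation antigen Mki67 (log2 1.75 ± 0.31 SE), the mitotic kinase Cdk1 (1.58 ± 0.21), Cdc20, which activates the anaphase-promoting complex (1.65 ± 0.23), and the cyclin Ccnb2 (2.01 ± 0.36). Outside the list, the spindle protein Nusap1 stood at 1.49 ± 0.20 (adjusted p 0.182). The list's adjusted p was 5.65e-28 with the preset correlation, 0.222 with an estimated correlation, and 0.0519 by fry. The extracellular matrix list was positive in 26 of 26 members (median 0.50) and 7 members passed adjusted over the list alone, among them the collagens Col1a1 (1.47 ± 0.25) and Col3a1 (1.15 ± 0.23). Its adjusted p was 8.44e-12 with the preset correlation, and the adjusted p was 0.222 with an estimated correlation. Col6a3, another collagen, had a log2 fold change of 0.98 ± 0.13 (adjusted p 0.182). Fibroblast markers were positive in 7 of 7 (median 0.78, adjusted p 0.00121 preset, and an adjusted p of 0.222 with an estimated correlation).

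The erythroid markers, which come with blood, were positive in 9 of 9 members beside these lists (median 0.84, adjusted p 4.18e-07 preset, and an adjusted p of 0.222 with an estimated correlation), 7 of them past the threshold over the list alone. The globin share was 0.203 ± 0.0698% with aldosterone and 0.112 ± 0.0309% in controls. Macrophage and other leukocyte markers were positive in 14 of 16 (median 0.40, adjusted p 0.00377 preset, and an adjusted p of 0.558 with an estimated correlation), with a median of -0.16 in batch 1 alone. Thick ascending limb markers, which belong to the tissue next to the inner medulla, were positive in 6 of 6 (median 0.67, adjusted p 0.00555 preset, and an adjusted p of 0.558 with an estimated correlation), with Umod, uromodulin, at 1.03 ± 0.37. Nuclear genes of oxidative phosphorylation were positive in 25 of 25, with a median of 0.33, and 22 passed over the list alone (adjusted p 1.25e-12 preset, and an adjusted p of 0.472 with an estimated correlation).

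**Figure D2:**
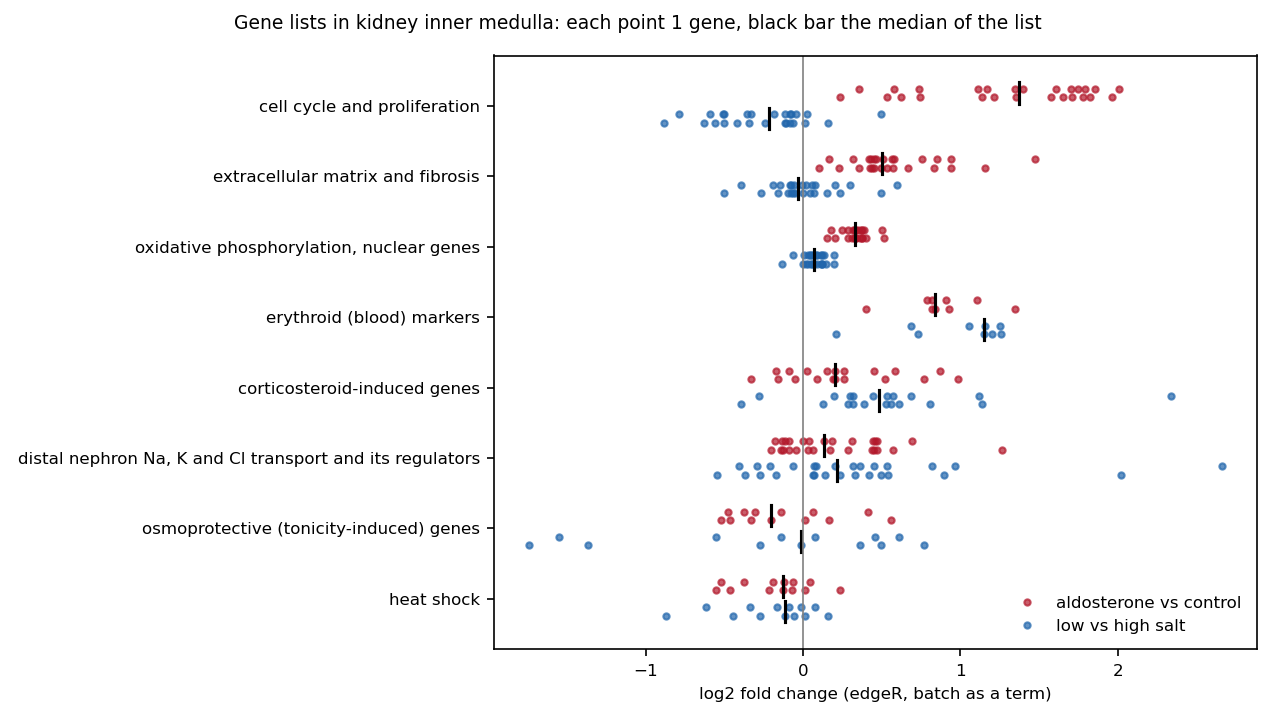
Log2 fold change of each member of 8 gene lists in the inner medulla, with aldosterone against control in red and low against high salt in blue; the x axis is the log2 fold change, the black bars are list medians. The cell cycle median is 1.37 with aldosterone and -0.21 with low salt, and the corticosteroid median 0.20 and 0.48.

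Of 19 corticosteroid-induced genes none passed over all genes and 3 passed over the list alone, Per1 (log2 0.52 ± 0.11), the deubiquitinase Usp2 (0.87 ± 0.20) and the pyruvate dehydrogenase kinase Pdk4 (0.58 ± 0.15). The list's median was 0.20, with an adjusted p of 0.0207 preset and an adjusted p of 0.222 with an estimated correlation. Zbtb16 stood at -0.05 ± 0.35, Sgk1 at -0.17 ± 0.18, Tsc22d3 at -0.33 ± 0.14 and Fkbp5 at 0.21 ± 0.18, with adjusted p-values of 0.972, 0.782, 0.495 and 0.736. The direction of Zbtb16 is not settled, as its log2 fold change ran from -0.31 to 0.47 when a library was left out. Control replicate 1 held 112 CPM of Zbtb16, against 28.6 to 41.8 CPM in the other controls. Of 27 Na, K and Cl transport genes Scnn1a alone passed over the list alone, and Scnn1b (0.04 ± 0.22) and Scnn1g (-0.13 ± 0.25) had adjusted p-values of 0.969 and 0.894 over all genes. The list's median was 0.13, with an adjusted p of 0.0430 preset and an adjusted p of 0.222 with an estimated correlation. Hsd11b2 (0.53 ± 0.25), Slc14a2 (-0.49 ± 0.14), Aqp2 (-0.16 ± 0.18) and Nr3c2 (-0.11 ± 0.09) did not pass, with adjusted p-values of 0.549, 0.319, 0.802 and 0.745. The smallest p-values among genes with lower values belonged to the adaptor Shb (-0.51 ± 0.07), the histone methyltransferase Ezh1 (-0.44 ± 0.07), Smkr1 (-0.58 ± 0.10), Gprasp1 (-0.40 ± 0.07) and Lgalsl (-0.36 ± 0.07), each with an adjusted p of 0.182.

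Further lists passed with the preset and not with an estimated correlation, with no member past the threshold over all genes: cholesterol synthesis (median 0.22, adjusted p 0.000429), fatty acid oxidation (0.12, 0.000988), glycolysis and hypoxia (0.18, 0.00117), intercalated cell markers (0.25, 0.0455) and, with lower values, heat shock (-0.13, 0.00377). With an estimated correlation the adjusted p-values of these 5 were 0.619, 0.222, 0.222, 0.638 and 0.366. The remaining lists did not pass, at medians of 0.44 for renin-angiotensin and corticosteroid receptors and enzymes, -0.06 for water and urea transport, -0.20 for osmoprotective genes and 0.03 for the circadian clock. They were -0.04 for immediate early genes, 0.11 for natriuretic peptide signalling, 0.06 for prostaglandin signalling, 0.09 for inflammatory genes, -0.09 for interferon-induced genes, -0.04 for endoplasmic reticulum stress and 0.08 for ribosomal protein genes. Among cell type markers, the medians were -0.14 for principal cells, 0.22 for the proximal tubule, 0.13 for the distal convoluted tubule, 0.48 for urothelium, 0.50 for smooth muscle, 0.05 for the endothelium, 0.10 for adipocytes and 0.13 for nerve and Schwann cells. The median and the mean differed in sign for immediate early genes, and the test gave a lower direction for the circadian clock against a positive median and mean. In all, 14 of 33 lists passed with the preset correlation, none with an estimated correlation, none by fry's directional test and 3 by its test in either direction. Without aldosterone replicate 4, 2 genes passed as lower.

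The responses to aldosterone and to low salt were compared by a test of their difference over the 16 kidney libraries. The difference passed for 10 of 18938 genes, 5 in each direction, and 2486 genes differed at an unadjusted p under 0.05. Srxn1, the sulfiredoxin that reactivates peroxiredoxins, had a log2 fold change of 0.38 ± 0.21 (SE) with aldosterone and fell on low salt (-1.95 ± 0.19), a difference of 2.30 ± 0.31 (adjusted p 0.0292). It also differed between the batches of the aldosterone experiment, at log2 1.77 ± 0.22 in batch 2 against batch 1 (edgeR adjusted p 0.0315). Shisa2 differed by 2.43 ± 0.33 (adjusted p 0.0292), Col6a3 by 1.40 ± 0.16 (0.0123) and Usp53 by -0.96 ± 0.14 (0.0292). Across 17491 genes, which are not independent replicates, the log2 fold changes of both comparisons correlated with a Pearson r of 0.10 (jackknife SE 0.16 over libraries, Spearman rho 0.11). The r was 0.23 over the 10294 genes with a mean of at least 10 CPM in both. Of the 454 genes called on low salt, 308 (67.8%) had the same sign with aldosterone, against 54.1% of all genes. In DESeq2, 24 genes were higher in both comparisons where 13.8 were expected (Fisher's exact test, p = 0.00625), and 10 lower in both where 3.003 were expected (p = 0.000712). The edgeR calls, with no gene called for aldosterone, gave none. Fisher's test and the shares of signs count genes as independent units, which they are not. Over libraries, the r of 0.10 lay within its jackknife SE of 0.

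The count of 10 fell to 0 without a batch term, and also without high-salt replicate 1, high-salt replicate 2, low-salt replicate 1 or low-salt replicate 3, and was 637 in DESeq2. It was 67 without high-salt replicate 4, 24 without low-salt replicate 4, 18 without control replicate 1 or 2, and 17 without control replicate 4. It was 4 without aldosterone replicate 4 or high-salt replicate 3, 3 without aldosterone replicate 3 or low-salt replicate 2, 2 without control replicate 3 and 1 without aldosterone replicate 2.

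In the heart ventricle, few genes passed on low salt: 2 were higher and 6 lower than on high salt among 15473 tested (edgeR, adjusted p under 0.05), and none passed with the replicate number as a block. Acta1, the skeletal alpha-actin of the fetal and overloaded heart, fell from 4088 ± 1621 to 1356 ± 439 CPM (SD, n = 4 rats), a log2 fold change of -1.56 ± 0.10 (SE) with an adjusted p of 0.00258, and of 0.0785 with the block. The Wnt receptor Fzd1 fell by 0.79 ± 0.07 on the log2 scale, Fbxl22, an F-box protein of the sarcomeric Z-disc, by 0.91 ± 0.09, the noncoding RNA Jpx by 1.85 ± 0.15 and the pseudogene Nid2-ps16 by 0.59 ± 0.07. The F-box protein gene Fbxo31 rose (0.49 ± 0.06). With the block, the adjusted p-values of these 5 were 0.128, 0.152, 0.134, 0.222 and 0.152. Snai3 (-2.81), which lies outside the naming rule and was named after its value was seen, and a higher gene with a provisional LOC name complete the 8. Of these, selected for a difference, 7 had no overlap between groups, and over all genes tested the share was 4.75%, where chance gives 2.86%. At an unadjusted p under 0.05 there were 879 higher and 762 lower genes, where chance gives 774 in all on average. The spread around that average is wider when genes vary together. Another split of the same libraries, with each batch spread evenly, gave 1618 such genes against 1641 in the real split. That count therefore does not set the diets apart from such a split. DESeq2 called 182 higher and 105 lower genes.

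The cardiac stress list, which holds genes raised in hypertrophy and wall stress, was lower as a group with the preset correlation. The list's adjusted p was 1.78e-09 with the preset correlation, 0.277 with an estimated correlation, and 0.0315 by fry. All 12 measured members had negative log2 fold changes with a median of -0.89, Acta1 fell over all genes tested, and 8 passed adjusted over the list alone. Nppb, the B-type natriuretic peptide, stood at 76.4 ± 16.8 CPM on low and 274 ± 137 CPM on high salt (log2 -1.84 ± 0.35, adjusted p 0.157), Ankrd1, a stretch-induced nuclear protein, at -1.07 ± 0.17 (0.105), and Rcan1, a target of calcineurin, at -0.79 ± 0.13 (0.105). Nppa (-2.69 ± 0.95, adjusted p 0.378) and Myh7 (-1.70 ± 0.81, adjusted p 0.501) varied widely. High-salt replicate 4 held 2509 and 4486 CPM against at most 300 and 1047 CPM in the 3 other high-salt hearts. The low-salt hearts ran from 16.7 to 201 CPM of Nppa and from 221 to 803 CPM of Myh7. Neither gene passed in any fit that left out a library. Myh7 had a log2 difference of 0.02 in batch 1 and of -3.08 in batch 2, and Nppb of -1.58 and -1.89.

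**Figure D3:**
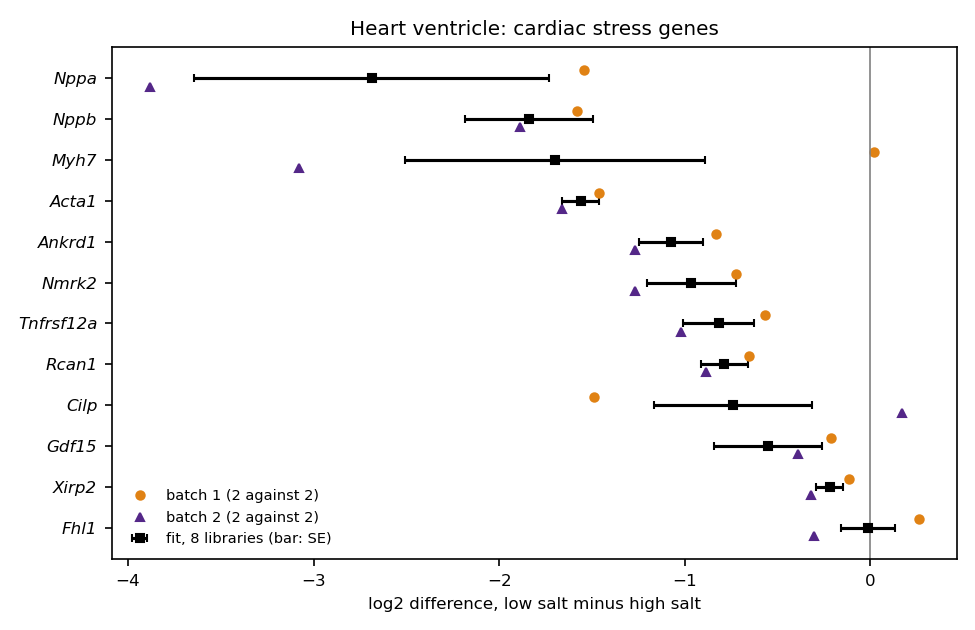
Log2 difference between low and high salt for the 12 cardiac stress genes in the heart ventricle, with the fit over 8 libraries (square, bar for the SE) and the differences within batch 1 (circle) and batch 2 (triangle); the x axis is the log2 difference. Acta1 is at -1.46 in batch 1 and -1.66 in batch 2, and Myh7 at 0.02 and -3.08.

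Extracellular matrix genes were negative in 25 of 26 members in heart, with a median of -0.38, and 6 passed adjusted over the list alone, among them Thbs1 (-1.12 ± 0.21) and Ccn1 (-0.60 ± 0.11). The list had an adjusted p of 4.73e-09 preset and an adjusted p of 0.754 with an estimated correlation. Genes of fatty acid oxidation were positive in 23 of 24 (median 0.20, adjusted p 7.25e-06 preset), with Acadm, which oxidises medium-chain fatty acids, at 0.25 ± 0.05, and oxidative phosphorylation genes in 25 of 25 (median 0.10, adjusted p 7.25e-06 preset). Both had an adjusted p of 0.754 with an estimated correlation. Corticosteroid-induced genes had a median of 0.21 (adjusted p 0.00163 preset, and an adjusted p of 0.754 with an estimated correlation) and 4 of 19 members passed over the list alone, Klf9 (0.59 ± 0.09), Usp2 (0.44 ± 0.10), Per1 (1.52 ± 0.36) and Tsc22d3 (0.34 ± 0.09). Zbtb16 (-0.16 ± 0.25), Fkbp5 (-0.00 ± 0.12) and Sgk1 (0.09 ± 0.14) had adjusted p-values of 0.845, 0.997 and 0.862. Nr3c2 (0.10 ± 0.09), Ace (0.07 ± 0.19) and Agtr1a (0.22 ± 0.22) did not pass, with adjusted p-values of 0.711, 0.915 and 0.749.

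Blood, tissue and batch differences accompanied these values. Erythroid markers were positive in 9 of 9 (median 1.29, adjusted p 0.00537 preset, and an adjusted p of 0.754 with an estimated correlation), with a median of 0.12 in batch 1 alone. Globin genes took 2.64 ± 1.42% of counts on low and 1.496 ± 1.23% on high salt. The sum of 10 proximal tubule markers, genes of the kidney cortex, was 56.3 to 180 CPM in the 4 heart libraries of batch 1 and 18.9 to 22.4 CPM in the 4 of batch 2. Batch itself separated 347 genes in heart (132 higher and 215 lower in batch 2), 24 in the aldosterone experiment and none in kidney on both diets, by edgeR with the same threshold. Fibroblast markers (median -0.30, adjusted p 0.0111), cell cycle genes (-0.51, 0.0342), cholesterol synthesis (-0.16, 0.00876), inflammatory (-0.19, 0.0342), interferon-induced (-0.16, 0.0332) and ribosomal protein genes (-0.10, 0.00131) passed with the preset correlation. With the replicate block, the cell cycle list did not (adjusted p 0.0828). With an estimated correlation their adjusted p-values were 0.754, 0.858, 0.754, 0.754, 0.808 and 0.754. In batch 2 alone the medians of the fibroblast and cell cycle lists were 0.08 and 0.89, and that of fatty acid oxidation -0.02.

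**Figure D4:**
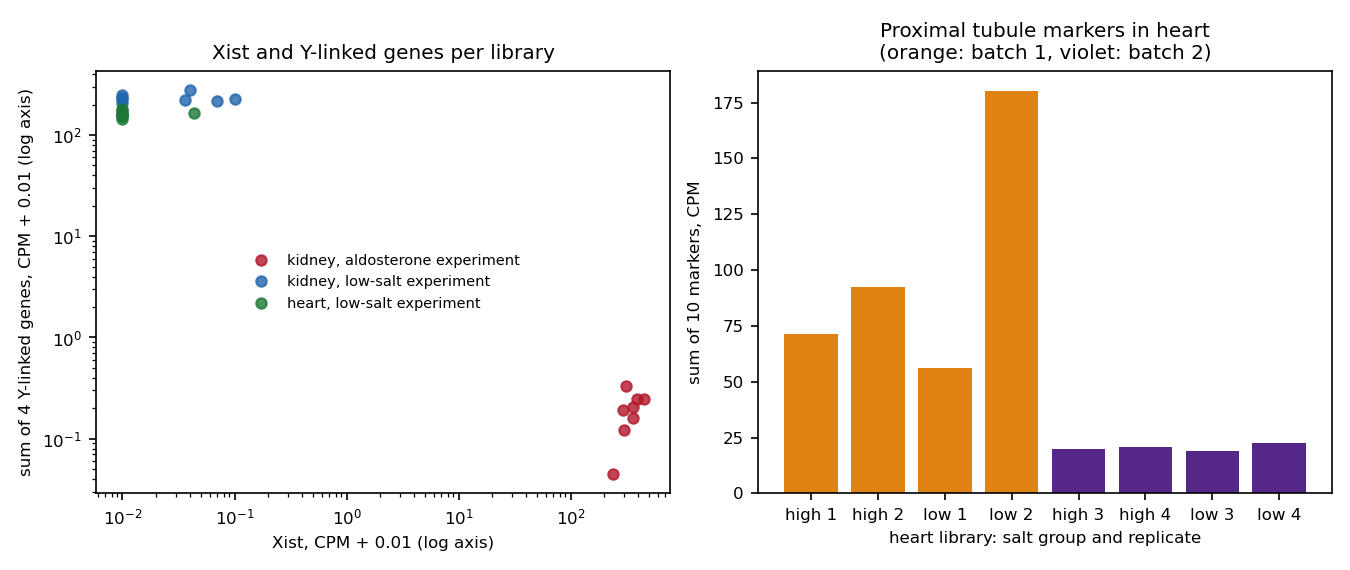
Left, the level of Xist against the summed level of 4 Y-linked genes in each of the 24 libraries, both in CPM + 0.01 on log axes, with the experiments in 3 colours. Right, bars of the summed CPM of 10 proximal tubule markers in each heart library, 56.3 to 180 CPM in batch 1 (orange) and 18.9 to 22.4 CPM in batch 2 (violet).

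The remaining heart lists did not pass, at medians of 0.04 for renin-angiotensin and corticosteroid receptors and enzymes, -0.10 for the circadian clock, 0.05 for immediate early genes, -0.04 for natriuretic peptide signalling and -0.09 for prostaglandin signalling. They were 0.05 for glycolysis and hypoxia, -0.03 for endoplasmic reticulum stress, 0.08 for heat shock, -0.02 for sarcomere genes and 0.02 for cardiac ion transport. Among cell type markers, the medians were -0.35 for atrial cells, 0.01 for smooth muscle, -0.05 for the endothelium, 0.13 for adipocytes, -0.13 for macrophages and other leukocytes, 0.06 for neutrophils and 0.19 for nerve and Schwann cells. The median differed in sign from the mean for immediate early genes and smooth muscle, and from the test for the renin-angiotensin, sarcomere, smooth muscle and neutrophil lists. In all, 12 of 29 lists passed with the preset correlation, none with an estimated correlation, 1 by fry's directional test and 8 by its test in either direction.

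Without a batch term, 1 heart gene passed, Jpx (adjusted p 0.0180), and Acta1 did not (0.282). Leaving out a library gave 1 called gene without high-salt replicate 2 or low-salt replicate 4, 2 without high-salt replicate 4 or low-salt replicate 1, and 3 without high-salt replicate 1 or low-salt replicate 3. It gave 4 without low-salt replicate 2 and 8, of which 4 were shared, without high-salt replicate 3. Acta1 passed in each of these 8 fits, Jpx in 5, Fzd1 in 3, Fbxl22 in 2, and Fbxo31 and Nid2-ps16 in 0.

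The responses to low salt in kidney and heart differed for 161 of 19408 genes, 73 with the higher value in kidney and 88 in heart, and for 2799 at an unadjusted p under 0.05. This test treats all libraries as independent rats, and any rat that gave both tissues is ignored. With the rat as a block across tissues, a fit chosen after the data had been seen, fewer genes passed. The 4 genes named here still did. Akr1b1 fell in kidney and had a log2 fold change of -0.02 ± 0.08 (SE) in heart, a difference of -1.71 ± 0.21. Rrad, a small GTPase that binds calcium channels, rose in kidney (1.00 ± 0.12) and stood at -0.26 ± 0.08 in heart, a difference of 1.27 ± 0.16. Fzd1 differed by 1.095 ± 0.13, at 0.30 ± 0.10 in kidney and -0.79 ± 0.07 in heart, and Ap1s3, an adaptor subunit of clathrin coats, by 1.36 ± 0.17. All 4 had an adjusted p of 0.0103 and passed in each of the 16 fits that left out a library. Without a batch term Akr1b1 alone passed, and the adjusted p-values were 0.0865 for Ap1s3, 0.0913 for Fzd1 and 0.0869 for Rrad. The log2 fold changes of kidney and heart correlated across 14579 genes with a Pearson r of 0.20 (jackknife SE 0.13, Spearman rho 0.11), and those of aldosterone and heart across 14467 genes with r of -0.07 (SE 0.15, rho -0.05). No gene was called in the same direction in both tissues by edgeR, where 0.024 higher and 0.0796 lower were expected, while DESeq2 gave 19 higher in both where 7.20 were expected (Fisher's exact test, p = 0.000102) and 9 lower where 5.15 were expected (p = 0.0718). The expected counts treat the tissues and the genes as independent. Deviations of rats that gave both tissues would raise the overlap and r without an effect of diet. Between aldosterone and heart, DESeq2 gave 4 genes higher in both where 2.68 were expected (Fisher's exact test, p = 0.279) and none lower, and edgeR none.

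The count of 161 was 826 in DESeq2, 14 without a batch term and 16 with the replicate block. It was 11 without heart high-salt replicate 2, 34 without heart low-salt replicate 4, 44 without heart high-salt replicate 3, and 45 without heart low-salt replicate 1. It was 48 without kidney high-salt replicate 3, 50 without kidney high-salt replicate 2, 53 without kidney low-salt replicate 3, 75 without kidney high-salt replicate 1, 83 without kidney low-salt replicate 4, 87 without heart low-salt replicate 2 and 93 without heart high-salt replicate 4.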

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

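The tests of the Y-linked pattern and the tests of blood, leukocytes and normalization for the cell cycle genes were chosen after those results had been seen, as was the count over splits with even batches; the tests of kidney transcripts in heart and of all 34 splits were not.

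Single libraries stood far from the 3 others of their group in 7 of 188 groups of values (named genes and library totals, ribosomal RNA and globin shares), where chance gives 9.4. In heart on high salt, replicate 4 held 4486 CPM of Myh7 (741 to 1047 in the others) and 2509 CPM of Nppa (102 to 300), and replicate 3 held 79.0 CPM of Zbtb16 (36.1 to 37.6). In the aldosterone experiment, control replicate 1 held 112 CPM of Zbtb16 (28.6 to 41.8) and aldosterone replicate 2 held 239 CPM of Ezh1 (223 to 225). In kidney, high-salt replicate 4 held 11.9 CPM of Ltb (6.32 to 7.22) and low-salt replicate 2 held 35.4 CPM of Srxn1 (22.2 to 24.3).

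The response to aldosterone differed from that to low salt for 10 genes, by an interaction test, with log2 differences of 1.40 for Col6a3, 2.30 for Srxn1, 2.43 for Shisa2 and -0.96 for Usp53. Of 30 groupings of the libraries within the experiments, the real one and otherwise drawn regroupings, 3 gave at least 10 genes, the real one among them. The highest other gave 221, so chance is not excluded. What set the regrouping with 221 genes apart was not tested. The response to low salt differed between kidney and heart for 161 genes, with log2 differences of 1.095 for Fzd1, -1.71 for Akr1b1, 1.36 for Ap1s3 and 1.27 for Rrad. Of 30 groupings, again the real one and otherwise drawn regroupings, the real one alone gave as many genes, and the highest other gave 59. These regroupings ignored the replicate number and any rat shared by both tissues. The real count is lower with either as a block, and no regrouping was made with them.

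Transcripts of the kidney proximal tubule appeared in the 4 heart libraries of batch 1, with Slc34a1 at 8.78 to 32.1 CPM against 0 to 0.0656 CPM in batch 2. Reads of the papilla libraries assigned to heart libraries would bring far more Aqp2 than proximal tubule transcripts, by a ratio of 15.5, and the ratio of the excesses was 0.0742, which argues against them as the whole source. Tissue or RNA from other parts of the kidney may be the source: 9 of 10 proximal tubule markers were higher in every batch 1 library than in every batch 2 library, but the share was 0.4 for markers of the thick ascending limb and distal convoluted tubule, which leaves this open. High-salt replicate 2 held the highest levels of Umod (47.8 CPM) and Aqp2 (20.9 CPM). No biological explanation was tested.

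All 16 libraries of the low-salt experiment had more Y-linked than Xist reads, while the labels describe female rats, and a count of 16 of 16 argues against a single mislabelled sample. The highest Xist level there was 0.0382% of the lowest in the aldosterone experiment, which argues against a mixture of RNA from both sexes. All 4 Y-linked genes reached 1 CPM in the 16 libraries and stayed below it in the 8 others, in line with male rats in the low-salt experiment, a hypothesis from the same data. Any difference between the aldosterone and low-salt responses is then confounded with sex as well as with the experiment.

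The cell cycle genes were higher in the aldosterone libraries, with a median log2 fold change of 1.37. More blood in these libraries is argued against as the cause by a cell cycle median of -0.21 in kidney on low salt, where the erythroid median (1.15) exceeded that with aldosterone (0.84) (in batch 1 alone it was -0.13, and in batch 2 alone 2.50 beside a cell cycle median of 0.19). A scaling factor moves all genes of a library alike, while the median was 1.37 for this list and 0.004 for all genes. This argues against the normalization as the source of that gap. A shift common to all genes cannot be seen in scaled values. The other scalings (lowest list median 1.37) moved the median of all genes by at most 0.01 and so tested little. More leukocytes may contribute, since the leukocyte median was 0.40 with aldosterone. In batch 1 alone that median was negative. The mean log2 level of the cell cycle list was nevertheless 3.81 to 4.30 with aldosterone and 2.45 to 3.02 in controls of that batch. These values argue against leukocytes as the whole source in batch 1. For batch 2 leukocytes stay open, as does an effect of aldosterone on proliferation. Of 34 splits of the 8 libraries 2 gave a median as large, with 1.46 as the highest other, while among the 18 with even batches, too few for a share under 0.05, the highest other was 1.11.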

How the results depend on the processing

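The fits of each batch alone, the rat as a block across tissues and the overlaps from DESeq2 calls were chosen after seeing the data. The named called genes, 29 in kidney, 6 in heart and 4 in each interaction, kept their direction in every fit without a library. The cause was not tested for the changes below, except that fits of 1 batch hold 4 libraries and an adjusted p under 0.10 is a looser threshold.

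With aldosterone, the counts of 0 higher and 0 lower genes became 297 and 62 in DESeq2, and higher genes became 1 at an adjusted p under 0.10, 4 without a filter and 1 in batch 1 alone. Without a library they were 0 to 0 higher and 0 to 2 lower. The 14 lists became 0 with an estimated correlation and 0 by fry, and 11 to 17 without a library. In kidney on low salt, 201 higher and 253 lower genes became 557 and 686 at an adjusted p under 0.10, 777 and 829 in DESeq2, 80 and 85 without a batch term, 7 and 7 against a fold of 1.2, 0 and 0 in batch 1 alone, and 36 lower in batch 2 alone. Without a library they were 2 to 295 higher and 0 to 171 lower. The 8 lists became 0 with an estimated correlation, 0 by fry, 5 with the stricter filter and 5 in batch 1 alone, and 4 to 9 without a library. In heart, 2 higher and 6 lower genes became 14 and 11 at an adjusted p under 0.10, 182 and 105 in DESeq2, and 48 and 37 without a filter. They became 0 and 1 without a batch term, 0 and 2 against a fold of 1.2, 1 higher by limma-voom, 1 and 0 in batch 1 alone and 0 and 1 in batch 2 alone. Without a library they were 0 to 4 higher and 1 to 4 lower. The 12 lists became 0 with an estimated correlation, 1 by fry and 5 in batch 2 alone, and 6 to 14 without a library.

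With the replicate block, the kidney low-salt counts became 30 higher and 22 lower, of which 47 are among the 454, and the heart counts 0 and 0. The block gave 0 genes for aldosterone against low salt and 16 for kidney against heart, and changed none of the counts of lists by over 1.5 times. In the kidney experiments the numbers are shared without pairing. There, 3 of 8 libraries with aldosterone and 2 of 8 on low salt correlated best with their own number. The pair correlations were -0.0454 to 0.3203 and -0.0470 to 0.231. In heart 3 of 8 libraries correlated best with their own number. Heart pairs lay at 0.223 to 0.296, against 0.258 to 0.325 for other numbers of the batch, so these correlations single out no pairs.

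The 10 genes that differed between aldosterone and low salt became 637 in DESeq2, 52 without a filter and 0 without a batch term, and 0 to 67 without a library. The 161 for kidney against heart became 826 in DESeq2, 14 without a batch term, 7 in batch 2 alone and 30 with the rat as a block, and 11 to 194 without a library. Overlaps of 0 became, in DESeq2, 24 higher and 10 lower for aldosterone and kidney, 19 and 9 for heart and kidney (1 and 1 at an adjusted p under 0.10) and 4 higher for aldosterone and heart. The correlations ran from -0.0111 to 0.170, 0.0825 to 0.228 and -0.110 to 0.0256 without a library.

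List medians or their tests turned direction in batch 1 alone for leukocyte markers with aldosterone (-0.16), erythroid markers in kidney on low salt (-0.13), and erythroid (0.12) and ribosomal protein genes (0.00793) in heart. In batch 2 alone in heart, medians or their tests turned for cell cycle (0.89), cholesterol synthesis (-0.00792), fatty acid oxidation (-0.0210) and fibroblast markers (0.0792), and so did the test of heart cell cycle genes without high-salt replicate 2 (-0.0640). Without a library, the last median ran from -0.910 to -0.0456.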

Other observations

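The 4 gene lists described here, and the test of whether kidney and heart came from the same rats, were chosen after the data had been seen. The lists were built from genes seen in these data, so they are not independent evidence, and their p-values are not adjusted.

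In kidney on low salt, 8 of 21 genes of the 26S proteasome regulatory particle, which unfolds ubiquitinated proteins, fell (limma camera, p = 7.81e-08 preset, p = 0.00321 with an estimated correlation, fry p = 1.31e-05), with a median log2 of -0.17. Psmd10 stood at -0.57 ± 0.09 (SE) and Psmd5 at -0.48 ± 0.07. Of 22 NF-kB subunits and TNF-family induced genes 8 rose (median 0.44, p = 2.43e-06 preset, p = 0.0255 with an estimated correlation, fry p = 0.00153), among them Birc3, an inhibitor of apoptosis (1.33 ± 0.20), Relb (0.89 ± 0.14) and Tnfrsf14 (1.31 ± 0.17). Another 6 of the 22 were negative, among them the chemokine gene Ccl2 at -2.50 ± 0.59 (adjusted p 0.0660), whose values did not overlap between the diets. Of 23 targets of NRF2, the regulator of the response to oxidants, 5 fell (median -0.42, p = 1.73e-05 preset, p = 0.152 with an estimated correlation, fry p = 0.0290), with Nqo1 at -1.71 ± 0.33 and Me1 at -1.21 ± 0.14. Nqo1 also differed between the batches of the aldosterone experiment, at log2 2.10 ± 0.21 in batch 2 against batch 1 (edgeR adjusted p 0.0177). No gene separated the batches of the kidney low-salt experiment. The medians of these 3 lists were -0.02, 0.07 and 0.01 with aldosterone and 0.03, -0.09 and 0.01 in heart, with no member called. In heart the NF-kB list was negative in 16 of 20 members (limma camera, p = 0.0297 preset, p = 0.239 with an estimated correlation, fry p = 0.225).

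In heart, 19 of 21 FoxO and muscle atrophy genes were positive on low salt with a median of 0.38 (p = 7.53e-15 preset, p = 0.0109 with an estimated correlation, fry p = 0.00103). Fbxo31 rose, although it passed in 0 of the 8 fits that leave out a library. Ulk1, a kinase that starts autophagy (0.63 ± 0.09), and the ubiquitin ligase Trim63 (0.40 ± 0.07) had adjusted p-values of 0.0813 and 0.111. The median of the list was 0.12 in kidney on low salt and -0.01 with aldosterone.

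Other splits of the 8 libraries of a comparison, 34 in each, were counted with the real split included. With aldosterone the real count is 0 genes, which all 34 reach by construction (up to 19), so that count decides nothing. As many lists as the real 14 came from 5, up to 16, so chance is not excluded for the lists. As many genes at an unadjusted p under 0.05 as the real 1750 came from 2, up to 2670. In kidney on low salt, the real split alone (1 of 34) gave as many genes as the real 454 (highest other 1) and a corticosteroid median as large as the real 0.48 (highest other 0.43). The corticosteroid list had an adjusted p of 0.866 with an estimated correlation and of 0.07 by fry's directional test. As many lists as the real 8 came from 12, up to 11. In heart, the real split alone (1 of 34) gave as many genes as the real 8 (highest other 5) and a cardiac stress median as large in size as the real 0.89 (highest other 0.82). No heart gene passed with the replicate block, and the list had an adjusted p of 0.277 with an estimated correlation. As many lists as the real 12 came from 6, up to 13. Of the 34 splits, 16 spread the batches unevenly over the groups, which was counted after the other results had been seen. The other 18 are too few for a share under 0.05, as the smallest they can give is 0.0556. Among those 18, the highest other values were 14 lists and 1586 genes at an unadjusted p under 0.05 with aldosterone. They were 0 genes and a corticosteroid median of 0.42 in kidney, and 5 genes and a cardiac stress median of 0.68 in heart. The 8 heart splits that part all 4 pairs of numbers are also too few, with 8 genes in the real split and 5 as the highest other.

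The same rats may have given kidney and heart, a hypothesis that the labels leave open. Of 640 variable genes among 12398 expressed in both tissues, 140 had correlations above 0.9 between kidney and heart libraries of the same diet and number, and 1 of 16 pairings, the labelled one, gave as many (highest other 87, exact p = 0.0625, the smallest that 16 pairings can give). Fam111a stood at 272 CPM in kidney and 257 CPM in heart of high-salt replicate 2, against 5.86 to 13.0 and 1.32 to 4.85 CPM in the others.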
